A study of Mus musculus with 18 samples.

How the data were processed

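Messenger RNA was sequenced from cross sections of mouse uterus at 12 weeks of age, in wild-type mice (WT) and in mice lacking Tsc2 in the uterus (KO), on a mixed 129Sv and C57BL/6 background. Per the labels, the uteri were flash frozen, RNA was prepared with an RNeasy plus mini kit, and stranded TruSeq libraries were read from a single end on a HiSeq2500. Each genotype was studied in 3 hormone states: with ovaries in place (intact), after removal of the ovaries at 4 weeks (ovx), and after removal of the ovaries at 4 weeks followed by a pellet of 0.5 mg 17β-estradiol with 90 days of release, carried for 8 weeks (E2). Every one of the 6 groups held 3 libraries, 18 in all. The numbers in the sample titles name the replicates, and 1 WT intact library with a compound number was taken as replicate 4. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between samples.

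The deposited table gives FPKM values computed by the authors with Cufflinks 2.0.2 and Cuffdiff, according to the submitters' processing notes, with a column per library and 25791 gene symbols, none listed more than once. The aligner, the annotation and the genome build were not given in the sources used here. The gene positions in the table were tested against GENCODE M21 on GRCm38, where 12.4% of 20401 matched symbols overlapped their position, so the positions are on another build and are printed only as the table gives them. FPKM summed to between 216032 and 591668 per library, and whether a further scaling between libraries had been applied is not given in the sources used here. FPKM tables hold no read counts, so the depth of each library is unknown and no counting intervals are given.

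Sets of libraries made together were looked for in the lowest values, which move in steps set by single reads, so that libraries processed alike share the same ratios of values gene by gene. For each pair of libraries, the largest share of genes up to 0.05 FPKM whose ratio fell within 0.02 log2 of each other was taken, and the libraries were clustered on this share into 4 sets, called batches 1 to 4 here. The share had a median of 7.33% over pairs within a batch, 2.91% over pairs in different batches with the ovaries alike in place or removed, and 1.47% between intact and ovariectomized libraries. The ranges over pairs of the first 2 kinds met (lowest 3.56%, highest 3.98%), and 3 of 3 other settings gave the same batches. Batch 1 held WT intact replicates 1 and 4 with KO intact replicates 1 and 4. Batch 2 held WT intact replicate 2 with KO intact replicate 3. Batch 3 held 7 libraries, namely WT ovx replicates 1 and 3, KO ovx replicates 1, 2 and 4, WT E2 replicate 5 and KO E2 replicate 3. Batch 4 held the other 5, namely WT ovx replicate 2, WT E2 replicates 1 and 2 and KO E2 replicates 1 and 2. The labels name no batches, so these sets rest on the values alone.

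Values were analysed as log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 3 of the 18 libraries were tested, which left 13898. A linear model with a mean per group was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a mean-variance trend), two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested within each of 10 comparisons, with an adjusted p under 0.05 as the threshold. The comparisons were KO against WT in each state and averaged over the 3 states, E2 against ovx and intact against ovx within each genotype, and the 2 differences between genotypes in the response to E2 and to the presence of ovaries. All fold changes are log2 differences of FPKM + 1 with the standard error (SE) of the model, a scale that understates the fold of genes with low values. Levels are mean FPKM ± SD with n = 3 libraries. Figures were drawn in Python 3.11.15.

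Tsc2 itself was tested by an exact two-sided permutation test in which genotype was permuted within each hormone state. Gene sets were 32 lists written from textbook knowledge of the uterus, the estrogen response, mTORC1 targets and cell types, of which 28 had at least 5 tested members. These were compared with all other genes by camera in limma with a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and camera was run again with the correlation estimated from the data. List members were counted past the threshold over all genes tested and also adjusted over the list alone. For genes called higher in KO E2 than in both WT E2 and KO ovx, and likewise for KO intact, the overlap was set against independent lists and against 100 simulations of unchanged groups that shared the KO libraries.

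Genes to be named were chosen by rule: adjusted p under 0.05, a mean of at least 5 FPKM in a compared group and, between groups of 3, no overlap between their libraries. Of these, the 10 with the largest change each way were taken in the KO against WT and E2 against ovx comparisons and the 5 largest each way in the others, passing over symbols of predicted or unnamed genes, and the 10 with the largest smaller change were taken from each overlap. From each list up to 4 called members with the smallest adjusted p were named, or up to 2 with the highest mean FPKM where none was called, and Tsc2, Tsc1, Esr1 and Pgr were taken in every comparison, with all of their calls given in the text. The tests, the filter, the lists, this rule and the alternatives of the next sentence were chosen before the data were examined. Those alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio scaling over 12169 genes (factors 0.75 to 1.26), quantile normalization, a fit to the compared groups alone, the replicate number as a factor, robust eBayes, a threshold of at least 2-fold, and leaving out each library of the compared groups in turn. The batch as a term in the model, fits within a batch, and the removal of WT intact replicate 4 together with KO ovx replicate 4 were added after the data had been seen. The intact and ovx libraries share no batch, so for intact against ovx the batch and the group cannot be told apart.

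The fit was tested on 13898 simulated genes with the pooled spread of these libraries and 100 changed genes of each size. At log2 1 and 2, KO against WT ovx recovered 41% and 91% of changed genes, and the mean over states 84% and 95%. Both differences between genotypes recovered 13% and 14% at log2 1 and 70% and 85% at log2 2. False calls numbered 4 to 9 per comparison, with equal spread simulated, while residual log2 SD was 0.137 in WT ovx and 0.316 in KO E2.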

Results

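RNA levels were measured in uteri of WT and KO mice in the intact, ovx and E2 states, with 3 libraries in each of the 6 groups. The title of the series concerns uterine genes that depend on estrogen and on mTORC1, the kinase complex restrained by TSC2. Of 25791 genes, 13898 reached 1 FPKM in at least 3 libraries and were tested. Genes listed at 0 numbered from 4228 in WT ovx replicate 1 to 7395 in WT intact replicate 4. Read totals were not given, and the relative depth inside a batch ran from 0.378 for KO E2 replicate 3 to 1 for WT ovx replicate 1. In WT E2 replicate 2, the symbol LOC236598 alone held 26.6% of all FPKM. The first 2 principal components carried 37.8% and 22.5% of the variance.

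**Figure D1:**
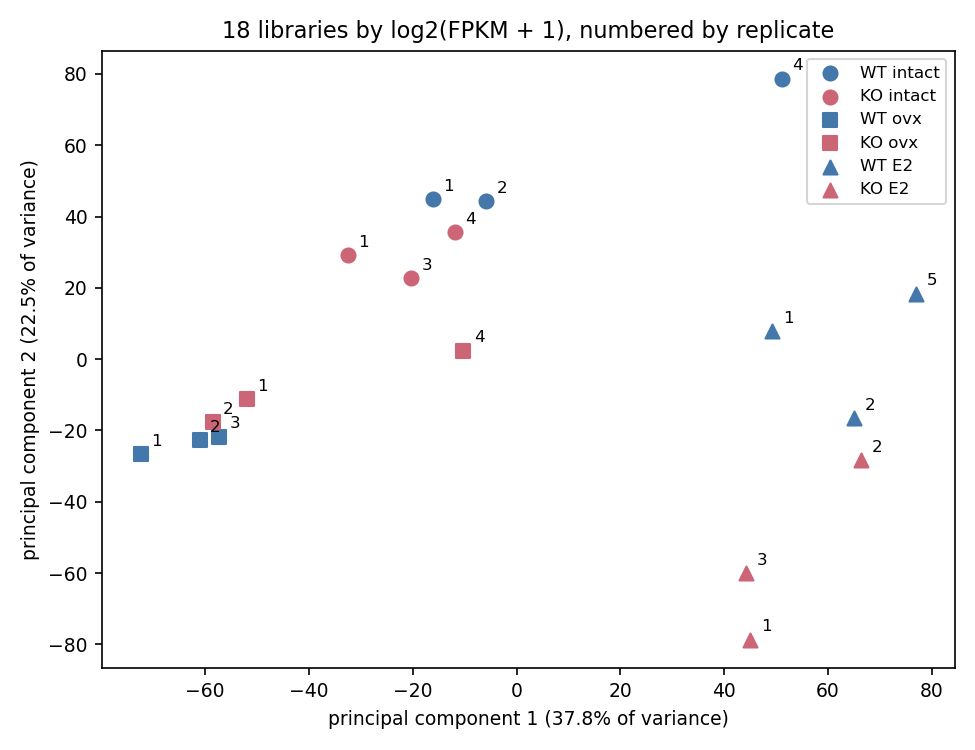
Principal components of log2(FPKM + 1) over the 13898 tested genes, each point a library, with component 1 (37.8% of variance) on the horizontal axis and component 2 (22.5%) on the vertical axis, coloured by group. KO E2 replicate 2 lay nearer to the WT E2 libraries, with which it had a mean r of 0.946, than to its own group at 0.898.

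Across genes, which are not independent replicates, Pearson's r between libraries of a group was lowest in WT intact (0.872 to 0.942) and KO E2 (0.892 to 0.935) while it was 0.974 to 0.986 in WT ovx and 0.913 to 0.988 in KO ovx. Besides KO E2 replicate 2, libraries stood apart in WT intact and KO ovx. WT intact replicate 4 had a mean r of 0.891 with its own group and 0.889 with WT E2. WT intact replicates 1 and 2 had a mean r of 0.907 and 0.926 with their own group and 0.927 and 0.937 with KO intact. KO ovx replicate 4 had a mean r of 0.921 with its group and held S100a8, a neutrophil calprotectin subunit, at 122 FPKM. Adipocyte genes were high in single libraries: Cfd, the adipsin gene, stood at 257, 0.104 and 1212 FPKM in the KO E2 replicates 1, 2 and 3 and at 47.6 in KO ovx replicate 4.

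Tsc2, the deleted gene (chromosome 17, start 24686894, end 24769574 in the table's own coordinates), was lower on average in KO libraries of every state. Its levels were 2.51, 2.25 and 2.04 FPKM in WT intact against 1.88, 1.98 and 1.62 in KO intact. In the ovx state they were 3.24, 3.49 and 3.17 in WT against 2.98, 3.33 and 2.39 in KO. In the E2 state they were 2.73, 2.38 and 2.66 in WT against 2.42, 1.75 and 2.28 in KO. The mean log2 difference over the states was -0.18, a ratio of 0.881 in FPKM + 1 (exact stratified permutation test, two-sided, p = 0.00275, where 0.00025 is the smallest p that the 8000 arrangements can give). The ratios of the mean FPKM itself were 0.807 for intact, 0.879 for ovx and 0.830 for E2. Within a state, the exact p was 0.1 for intact, 0.3 for ovx and 0.2 for E2, and 3 libraries against 3 cannot go below 0.1. In limma, which tested the gene among all others, the mean difference of -0.18 ± 0.07 (SE) had an adjusted p of 0.158. Tsc1, whose product binds TSC2, did not pass the test in the same comparison (0.11 ± 0.08, adjusted p = 0.403). Between hormone states Tsc2 was lower in intact than in ovx libraries (-0.40 ± 0.13 in WT and -0.46 ± 0.13 in KO). Tsc1 was lower in E2 than in ovx libraries (-0.45 ± 0.13 in WT and -0.49 ± 0.13 in KO) and in intact than in ovx WT libraries (-0.36 ± 0.13). Each of these 5 calls ended without 1 to 5 of the 6 libraries compared.

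**Figure D2:**
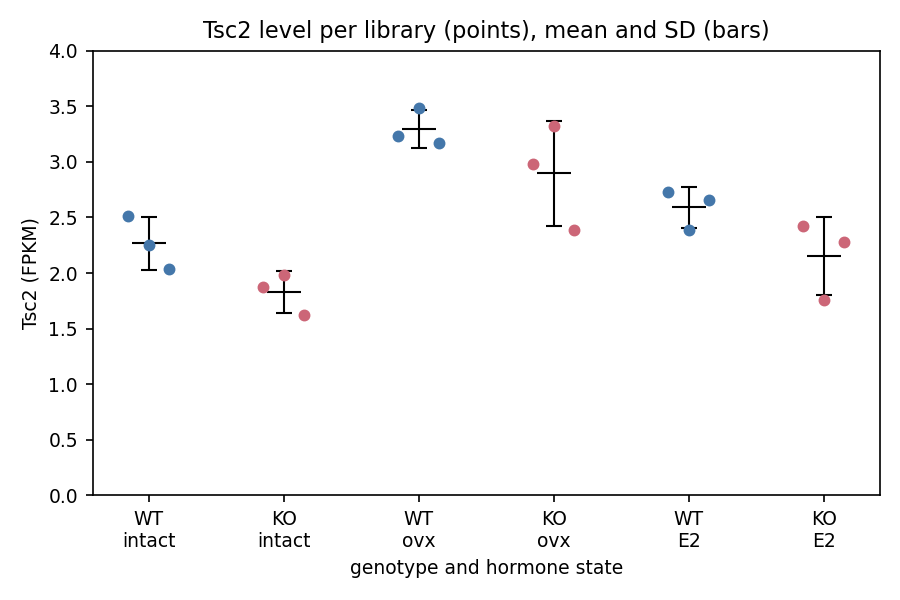
Tsc2 level in FPKM (vertical axis) in each library of the 6 groups on the horizontal axis, with the mean and SD of 3 libraries per group. Group means were 2.27 and 1.83 FPKM for WT and KO intact, 3.30 and 2.90 for ovx, and 2.59 and 2.15 for E2.

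KO and WT were compared in intact mice. Estrous stage was not given, so it cannot be told from genotype. Rnase1, a secreted ribonuclease, rose from 0.205 ± 0.178 to 23.7 ± 19.0 FPKM (SD, n = 3), a log2 change of 4.10 ± 0.71, adjusted p = 0.00954. Fst, which encodes the activin antagonist follistatin, rose from 0.0612 ± 0.0617 to 4.17 ± 1.98 FPKM (2.21 ± 0.21, adjusted p = 0.000377), and Wif1, a secreted WNT inhibitor, rose by 1.98 ± 0.24. Genes of other secreted ribonucleases rose as well, by 3.11 for Ang2, 2.92 for Ang6 and 3.00 for Rnase4, and Gpx3, the extracellular glutathione peroxidase, rose by 3.55 ± 0.72. Serpinb11 (a serpin), Mustn1, C1qtnf3 and the tight junction gene Cldn2 rose by 3.44, 3.33, 3.26 and 2.87, while clusterin (Clu) rose by 2.97. Prap1, a secretory product of the uterine epithelium, fell from 455 ± 356 to 3.44 ± 1.99 FPKM (-6.02 ± 1.19, adjusted p = 0.019). The alpha-1-antitrypsin genes Serpina1a, Serpina1b, Serpina1c, Serpina1d and Serpina1e fell together, with log2 changes of -5.52, -5.64, -5.64, -5.48 and -5.68, and are near-identical paralogs whose reads cannot be assigned with certainty. Fxyd4, a regulator of the sodium pump, fell by 5.60 ± 0.77 on the log2 scale, and Gcnt3, a mucin glycosyltransferase, fell by 3.01 ± 0.55. Of 48 named genes called here, 18 were called without each of the 6 libraries in turn, among them Rnase1, Fst, Wif1, Serpinb11, Mustn1, C1qtnf3, Cldn2, Fxyd4 and the 5 Serpina1 genes. Without KO intact replicate 3 the adjusted p was 0.104 for Gpx3, 0.204 for Clu, 0.097 for Prap1, 0.06 for Rnase4 and 0.0784 for Gcnt3. Without WT intact replicate 4 it was 0.056, 0.111, 0.0729 and 0.0634 for Gpx3, Clu, Prap1 and Rnase4, and the calls of Gpx3, Clu and Rnase4 also ended without KO intact replicate 4, at 0.0656, 0.118 and 0.0666. Without KO intact replicate 1 Gpx3 and Prap1 had 0.062 and 0.0671, and without WT intact replicates 1 and 2 Clu had 0.0516 and 0.072.

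Muscle and vessel list medians rose in KO intact uteri. Of 18 smooth muscle contractile genes, 2 rose over all genes tested and 16 adjusted over the list alone, with a list median of 2.01 and a camera adjusted p of 3.11e-13 (adjusted p = 0.389 with an estimated correlation). Des, which encodes the intermediate filament desmin, went from 18.9 ± 13.2 to 113 ± 27.4 FPKM (2.76 ± 0.63, adjusted p = 0.0395), and tropomyosin Tpm1 rose by 1.88 ± 0.45. Among 14 blood endothelium genes, 4 rose (13 adjusted over the list alone), namely Vwf (1.34), Ptprb (1.51), Erg (1.11) and Pecam1 (2.04). The endothelial median was 1.36 with an adjusted p of 1.16e-12 (adjusted p = 0.285 with an estimated correlation). Lymphatic genes moved likewise: 4 of 8 rose (6 adjusted over the list alone), including Flt4, the receptor of VEGF-C, by 1.61 ± 0.29, the hyaluronan receptor Lyve1 by 2.23 ± 0.45 and Mmrn1 by 2.09. The lymphatic median was 1.51 with an adjusted p of 8.58e-08 (adjusted p = 0.285 with an estimated correlation). Stroma genes had a median of 0.79, macrophage genes -0.21 and lymphocyte genes -0.01 (-0.006), and uterine epithelium genes -0.84, with 0 of 20 epithelial genes called (3 lower adjusted over the list alone). Erythrocyte genes, 3 tested, rose with them by a median of 2.20, with 1 called over all genes (3 adjusted over the list alone), Hbb-b1 (2.46 ± 0.58, adjusted p = 0.0423). The Hbb-b1 call held only without WT intact replicate 2. Without WT intact replicate 4, KO intact replicate 1 or KO intact replicate 3, 0 smooth muscle genes were called, and 11 and 4 were called without WT intact replicate 2 and KO intact replicate 4. For the endothelial genes the number was 7 without WT intact replicate 1, 2 without KO intact replicate 1 or 4, and 0 without WT intact replicate 4 or KO intact replicate 3. For the lymphatic genes it was as low as 0, without KO intact replicate 3. Within batches 1 and 2 the medians were 2.38 and 1.39 for smooth muscle, 1.09 and 1.70 for endothelium and 1.51 and 1.47 for the lymphatic list.

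Smaller groups also moved in intact mice. Among WNT and hedgehog response genes, Wif1 and Sfrp4 (2.47), both secreted WNT antagonists, rose among 11 tested (4 adjusted over the list alone). The WNT and hedgehog median was 0.77 with an adjusted p of 8.59e-06 (adjusted p = 0.285 with an estimated correlation). Rragd, a GTPase that recruits mTORC1 to lysosomes, rose by 1.36 ± 0.21, adjusted p = 0.00507, and the melanosomal genes Gpnmb and Mlana by 2.33 and 1.47. The lysosome list of 30 had a median of 0.26 and an adjusted p of 0.00668 (adjusted p = 0.854 with an estimated correlation), with 2 members higher (9 higher and 2 lower adjusted over the list alone). Interferon response genes had a median of -1.21 and an adjusted p of 0.000348 (adjusted p = 0.854 with an estimated correlation), with 1 of 18 lower, Irf7 (-2.49), and 6 lower adjusted over the list alone. Of 29 estrogen-induced genes, Ctgf (2.48) and Inhbb (2.78) rose and Prap1 fell, and the list had a median of -1.11 (adjusted p = 0.0679). Esr1, the estrogen receptor, and Pgr, the progesterone receptor, did not pass the test (-0.06 ± 0.33, adjusted p = 0.951 and -1.02 ± 0.41, adjusted p = 0.198). The calls of Gpnmb and Mlana ended without any of the 6 libraries (adjusted p up to 0.18 and 0.175). Those of Sfrp4 and Irf7 ended without WT intact replicate 4 or any KO intact library (up to 0.156 and 0.185), and for Irf7 also without WT intact replicate 2 (0.0691).

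In all, 303 genes differed between KO and WT in intact mice, 165 higher and 138 lower in KO, and 245 of them by at least 2-fold. At 22.8% of tested genes the KO and WT libraries did not overlap, where chance gives 10%. The number called was 674 without WT intact replicate 1, 460 without replicate 2 and 132 without replicate 4 of the same group, and 100, 66 and 155 without KO intact replicates 1, 3 and 4. With batch as a term 262 genes were called (164 higher, 98 lower), and within batches 1 and 2, with the spread pooled over all libraries, 19 (2 libraries against 2) and 5 (1 against 1).

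**Figure D3:**
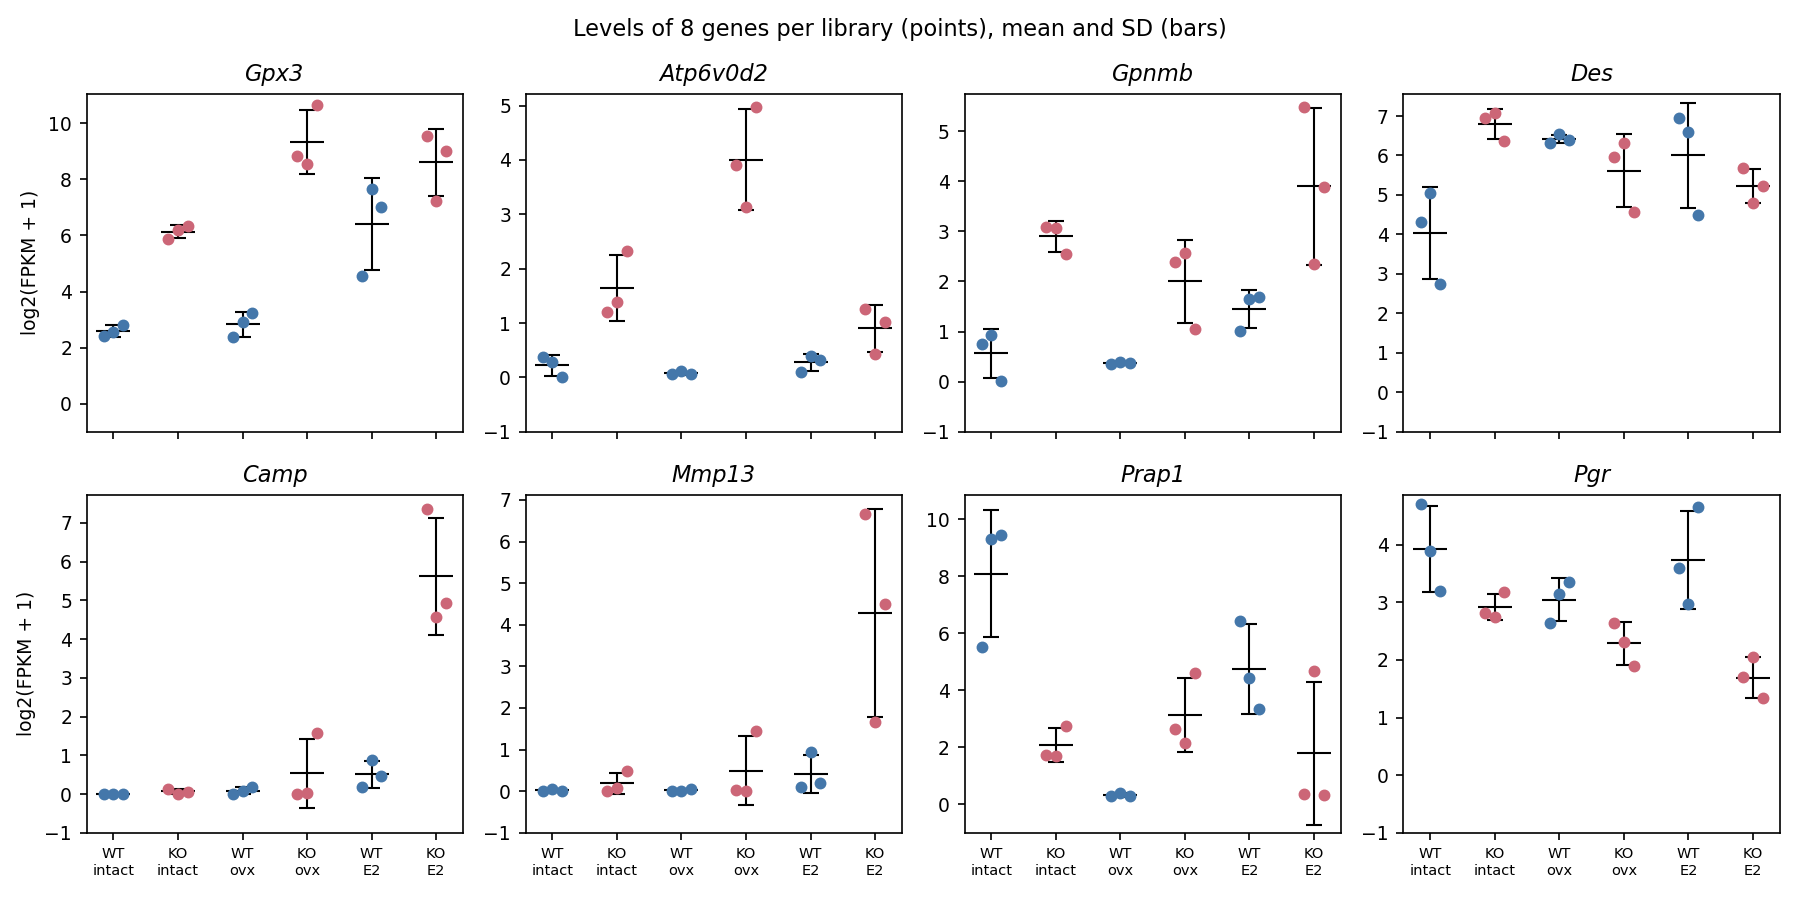
Levels of Gpx3, Atp6v0d2, Gpnmb, Des, Camp, Mmp13, Prap1 and Pgr as log2(FPKM + 1) on the vertical axis of each panel, by group on the horizontal axis, with a point per library and the mean and SD of 3 libraries. Gpx3 averaged 6.32 FPKM in WT ovx and 810.2 in KO ovx, and Camp 0.452 in WT E2 and 71.5 in KO E2.

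KO and WT were next compared without ovarian hormones, in the ovx state. Gpx3 rose from 6.32 ± 2.09 to 810.2 ± 689 FPKM (SD, n = 3), a log2 change of 6.51 ± 0.72, adjusted p = 0.000222. Its paralogs Gpx6 and Gpx5 rose by 4.93 and 4.25 in a near-constant ratio to it, so that reads shared with Gpx3 cannot be excluded. Fxyd2, the gamma subunit of the sodium pump, rose from 1.09 ± 0.421 to 146 ± 131 FPKM (5.80 ± 0.50, adjusted p = 1.57e-05), and Cyp26a1, which degrades retinoic acid, from 0.122 ± 0.0514 to 33.1 ± 36.9 FPKM (4.38 ± 0.52, adjusted p = 0.000274). Further genes also rose: Pdzk1ip1 by 4.27, the inositol transporter Slc5a11 by 4.14, the beta-defensin Defb1 by 3.88 and the carbonic anhydrase Car4 by 3.74. Tnni2, a fast-muscle troponin, fell from 14.3 ± 1.54 FPKM in WT (-2.63 ± 0.31, adjusted p = 0.000259), the noncoding transcript Meg3 fell by 2.02 ± 0.35 on the log2 scale, and Sned1 fell by 1.70 ± 0.21. All of these genes were called without each of the 6 libraries in turn. Gprasp2 fell by 1.34 ± 0.26 on the log2 scale, with an adjusted p of 0.0702 without WT ovx replicate 1. Col15a1, a basement membrane collagen, and the secreted Crispld2 changed by -1.76 and -1.85. The call of Col15a1 ended without any of the 6 libraries (adjusted p up to 0.13), and that of Crispld2 without any but KO ovx replicate 2 (up to 0.129).

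Lysosomal genes rose in KO ovx uteri. Of 30 lysosome and MiT/TFE target genes, 13 rose and 0 fell over all genes tested (21 adjusted over the list alone). The lysosome median was 0.97 with a camera adjusted p of 1.24e-12 (adjusted p = 0.639 with an estimated correlation). Atp6v0d2, a subunit of the proton pump, went from 0.0548 ± 0.0219 to 17.4 ± 11.7 FPKM (3.93 ± 0.37, adjusted p = 4.48e-05). Rragd rose by 2.79 ± 0.21, adjusted p = 5.41e-06, the sialidase Neu1 by 2.73 ± 0.31 and the hexosaminidase subunit Hexa by 1.89 ± 0.25. These 4 genes were called without each library in turn, while the count for the list was 6, 7 and 7 without WT ovx replicates 1, 2 and 3 and 8 and 7 without KO ovx replicates 1 and 4. Genes of oxidative phosphorylation encoded in the nucleus moved the same way, with 10 of 26 higher and 0 lower (21 adjusted over the list alone), a median of 0.82 and an adjusted p of 2.91e-10 (adjusted p = 0.639 with an estimated correlation). Examples were Cox5a (2.08 ± 0.43) and Cox6c (1.13 ± 0.22), subunits of cytochrome c oxidase, and Ndufa1 (1.49 ± 0.27) of complex I. Without WT ovx replicate 1 their adjusted p was 0.0903, 0.0677 and 0.0504, and without KO ovx replicate 4 it was 0.0571 for Cox5a. The oxidative count depended on single libraries, with 0, 5 and 3 genes without WT ovx replicates 1, 2 and 3 and 5 and 2 without KO ovx replicates 1 and 4. Within batch 3 the medians were 1.00 (0.998) for the lysosome list and 0.89 for the oxidative list, with 5 and 2 genes called, and with batch as a term 8 and 6 genes were called.

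Epithelium, vessel, stroma, translation and interferon lists in ovx passed camera only at the preset correlation. The uterine epithelium list had a median of 1.33 and an adjusted p of 0.00258 (adjusted p = 0.764 with an estimated correlation). Of its 20 genes 1 rose (2 adjusted over the list alone), the tight junction gene Cldn4 (2.16). Its adjusted p was 0.156, 0.0792 and 0.09 without WT ovx replicates 1, 2 and 3 and 0.0811 and 0.15 without KO ovx replicates 1 and 4. Endothelial and stromal genes had medians of -0.64 and -0.95 with adjusted p values of 1.45e-06 and 0.000541 (adjusted p = 0.639 and 0.657 with an estimated correlation). Of their 14 and 12 genes 0 were called in limma, over all genes or adjusted over the list alone. Cytosolic translation genes had a median of -0.38 and an adjusted p of 1.92e-08 (adjusted p = 0.707 with an estimated correlation). Of 34 such genes 1 fell over all genes tested and 0 adjusted over the list alone, with 4 lower without KO ovx replicate 4 but 0 without any of the other 5 libraries. Interferon response genes had a median of 0.92 and an adjusted p of 0.00891 (adjusted p = 0.764 with an estimated correlation). Of 18 such genes 1 rose (5 adjusted over the list alone), 3 without KO ovx replicate 2 and 0 without KO ovx replicate 1 or any WT ovx library. Esr1 and Pgr did not pass the test (-0.47 ± 0.33, adjusted p = 0.453 and -0.76 ± 0.41, adjusted p = 0.307).

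In the ovx state 753 genes differed, 643 higher and 110 lower in KO, and at 40.2% of tested genes the libraries did not overlap, where chance gives 10%. Median-ratio scaling moved the median gene by -0.13 log2 and gave 669 higher and 399 lower, so that the higher share went from 85.4% to 62.6%, and quantile normalization gave 51.5%. The number called was 149, 309 and 259 without WT ovx replicates 1, 2 and 3, 350 without KO ovx replicate 1 and 312 without KO ovx replicate 4. With batch as a term 429 genes were called (353 higher and 76 lower), and within batch 3, the only batch with both genotypes in this state, 152.

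Under E2 the comparison of KO with WT asked how loss of Tsc2 changed the uterus at a fixed estradiol supply. Camp, which encodes the antimicrobial cathelicidin of neutrophil granules, rose from 0.452 ± 0.358 to 71.5 ± 78.4 FPKM (SD, n = 3), a log2 change of 5.11 ± 0.54, adjusted p = 0.000199. Ngp, another neutrophil granule gene, rose from 0.698 ± 0.511 to 117 ± 148 FPKM (5.22 ± 0.78, adjusted p = 0.00096), and Slpi, a secreted protease inhibitor, from 12.3 ± 5.59 to 459.9 ± 410.0 FPKM (4.35 ± 0.89, adjusted p = 0.00729). Scgb3a1, a secretoglobin, fell from 918 ± 588 to 28.1 ± 45.1 FPKM (-6.43 ± 0.97, adjusted p = 0.00107), the complement regulator C4bp fell by 3.92 ± 0.49 on the log2 scale, and Cbs, a cystathionine synthase, fell by 3.36 ± 0.47. The peptide transporter Slc15a2 fell by 3.42 ± 0.70. Pgr fell from 14.0 ± 9.10 to 2.30 ± 0.805 FPKM (-2.05 ± 0.41, adjusted p = 0.00652) and Esr1 from 5.99 ± 3.64 to 1.27 ± 0.688 FPKM (-1.54 ± 0.33, adjusted p = 0.0095). Apart from Esr1 (adjusted p = 0.0567 without KO E2 replicate 1), these genes were called without each of the 6 libraries in turn. The protease gene Mmp3, the cysteine protease inhibitors Ctla2a and Ctla2b, the mucin-like Fcgbp, the chemokine Cxcl17, Spink12 and Serpina9 changed by 4.36, 3.84, 3.90, -4.72, -3.95, -4.16 and -3.52. Their calls ended without WT E2 replicate 1 or 5 or KO E2 replicate 1 or 3, and without KO E2 replicate 1 the adjusted p ran from 0.0556 for Fcgbp to 0.12 for Serpina9. Stefin genes Stfa3, Stfa2l1 and Stfa2, paralogs with similar sequence, rose by 4.15, 4.02 and 3.92, and lost the call without any WT E2 library or KO E2 replicate 1 (adjusted p = 0.189, 0.0726 and 0.106 without the latter).

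Genes of neutrophils and their chemokines formed the group with the most members called in KO E2 uteri. Of 19 tested, 13 rose and 0 fell (15 adjusted over the list alone). The neutrophil median was 2.51 with a camera adjusted p of 1.16e-16 (adjusted p = 0.387 with an estimated correlation). The number called stayed between 11 and 14 with any library left out. Besides Camp and Ngp, the granule protease genes Elane (2.04 ± 0.25) and Prtn3 (2.71 ± 0.36) and the receptor gene Csf3r (2.22 ± 0.23) rose. Within batch 3 the median of the list was 1.67 with 0 genes called in limma, and within batch 4 it was 2.84 with 2. Lymphocyte genes rose in 5 of 10 cases (8 adjusted over the list alone), among them the common leukocyte antigen Ptprc (1.94 ± 0.28) and Cd3g (1.34 ± 0.27). The lymphocyte median was 1.15 with an adjusted p of 2.9e-07 (adjusted p = 0.387 with an estimated correlation). Without WT E2 replicate 1 or 5, 2 were called. Macrophage genes had a median of 1.13 and the same adjusted p values, and 2 of 15 rose. These were Csf1r (2.22 ± 0.45) and Fcgr1 (1.11 ± 0.21), against 11 adjusted over the list alone and 7 without KO E2 replicate 2. Beside these cells, 0 of 9 adipocyte genes were called in limma over all genes and 6 adjusted over the list alone (median 2.83, adjusted p = 0.000186, and adjusted p = 0.496 with an estimated correlation). The adipocyte median was 6.48 within batch 3 and 1.01 within batch 4, and without KO E2 replicate 2 all 9 were called. Erythrocyte genes, 3 tested, had a median of 1.41 and 0 calls over all genes (3 adjusted over the list alone).

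Matrix genes rose in the same comparison. Among 25 matrix proteases and inhibitors, 9 rose (16 adjusted over the list alone), including the collagenase Mmp13 (3.87 ± 0.80), the gelatinase Mmp9 (3.27 ± 0.51) and Mmp8 (2.73 ± 0.56), the latter also neutrophil genes. The protease median was 1.29 with an adjusted p of 4.72e-09 (adjusted p = 0.387 with an estimated correlation). The count was 5 without WT E2 replicate 1 or 5 or KO E2 replicate 1, and 16 without KO E2 replicate 2. Of 24 fibrillar matrix genes 6 rose (11 adjusted over the list alone), among them thrombospondin Thbs2 (3.83 ± 0.56, adjusted p = 0.000905). The fibrillar median was 1.59 with an adjusted p of 4.72e-09 (adjusted p = 0.436 with an estimated correlation). Of these genes 1 was called without WT E2 replicate 1, 2 or 5 or KO E2 replicate 1 or 3, and 18 without KO E2 replicate 2. Lysosome genes rose in 7 of 30 cases (12 adjusted over the list alone), including Hexa (1.30 ± 0.25), the folliculin gene Flcn (0.92 ± 0.18) and Gpnmb (2.45 ± 0.57). The lysosome median was 0.63 with an adjusted p of 4.2e-08 (adjusted p = 0.395 with an estimated correlation). For that list 2 were called without WT E2 replicate 1, 4 and 3 without KO E2 replicates 1 and 3, and 13 without KO E2 replicate 2. Gpnmb itself had an adjusted p of 0.0751 without WT E2 replicate 1, 0.0702 without KO E2 replicate 1 and 0.0511 without KO E2 replicate 3.

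Epithelial and estrogen-induced medians fell in KO E2 uteri. Of 29 estrogen-induced uterine genes 5 fell and 0 rose (10 lower adjusted over the list alone). The estrogen-induced median was -1.90 with an adjusted p of 3.32e-05 (adjusted p = 0.496 with an estimated correlation). Besides Pgr these included the connexin Gjb2 (-2.76 ± 0.64) and the mucin Muc1 (-3.21 ± 0.89). For Gjb2 the adjusted p was 0.0608, 0.0549 and 0.0831 without WT E2 replicate 1, WT E2 replicate 5 and KO E2 replicate 1, and Muc1 kept its call only without KO E2 replicate 2 (adjusted p up to 0.149 without KO E2 replicate 1). Single libraries moved this count to 1 (without WT E2 replicate 1 or 5 or KO E2 replicate 1), to 2 without KO E2 replicate 3, and to 12 lower and 1 higher without KO E2 replicate 2. Of 20 uterine epithelium genes 6 fell and 0 rose (11 lower adjusted over the list alone), including the epithelial transcription factors Ehf (-2.14 ± 0.47) and Grhl2 (-1.39 ± 0.36), the protease Prss8 (-1.68 ± 0.39) and the splicing regulator Esrp1 (-1.61 ± 0.40). The epithelial median was -1.51 with an adjusted p of 9.71e-07 (adjusted p = 0.436 with an estimated correlation). Without WT E2 replicate 5 the adjusted p of Ehf, Grhl2, Prss8 and Esrp1 was 0.0663, 0.129, 0.0595 and 0.1, and without KO E2 replicate 1 it was 0.0564, 0.15, 0.0758 and 0.116. The epithelial count was 0 without WT E2 replicate 5 or KO E2 replicate 1, 1 without WT E2 replicate 1, 2 without KO E2 replicate 3 and 11 without KO E2 replicate 2. Within batches 3 and 4 the medians were -2.87 and -1.13 for the estrogen-induced list and -1.57 and -1.52 for the epithelial list.

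Between KO and WT under E2, 1180 genes differed, 682 higher and 498 lower in KO, 863 of them by at least 2-fold, and at 22.5% of tested genes the libraries did not overlap, where chance gives 10%. The number called was 517 and 544 without WT E2 replicates 1 and 5, 526 and 640 without KO E2 replicates 1 and 3, and 2235 without KO E2 replicate 2. That library lay nearer to the WT E2 group, but its Tsc2 level was the lowest of the E2 libraries, and its neutrophil mean log2 level of 4.04 was above those of WT E2 (1.82, 2.64 and 2.67). No WT E2 library lay nearer to KO E2, so a swap between the 2 groups lacks a partner. A single wrong label and a weakly affected animal both stay open. A fit to these 6 libraries alone called 0 genes in limma, with 2473 at an unadjusted p under 0.05. With batch as a term 1016 genes were called (622 higher and 394 lower), and within batches 3 and 4, 279 and 18. Batch 3 holds 1 library of each genotype here, KO E2 replicate 3 and WT E2 replicate 5, so its count rests on the spread of other groups, and batch 4 holds 2 of each.

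**Figure D4:**
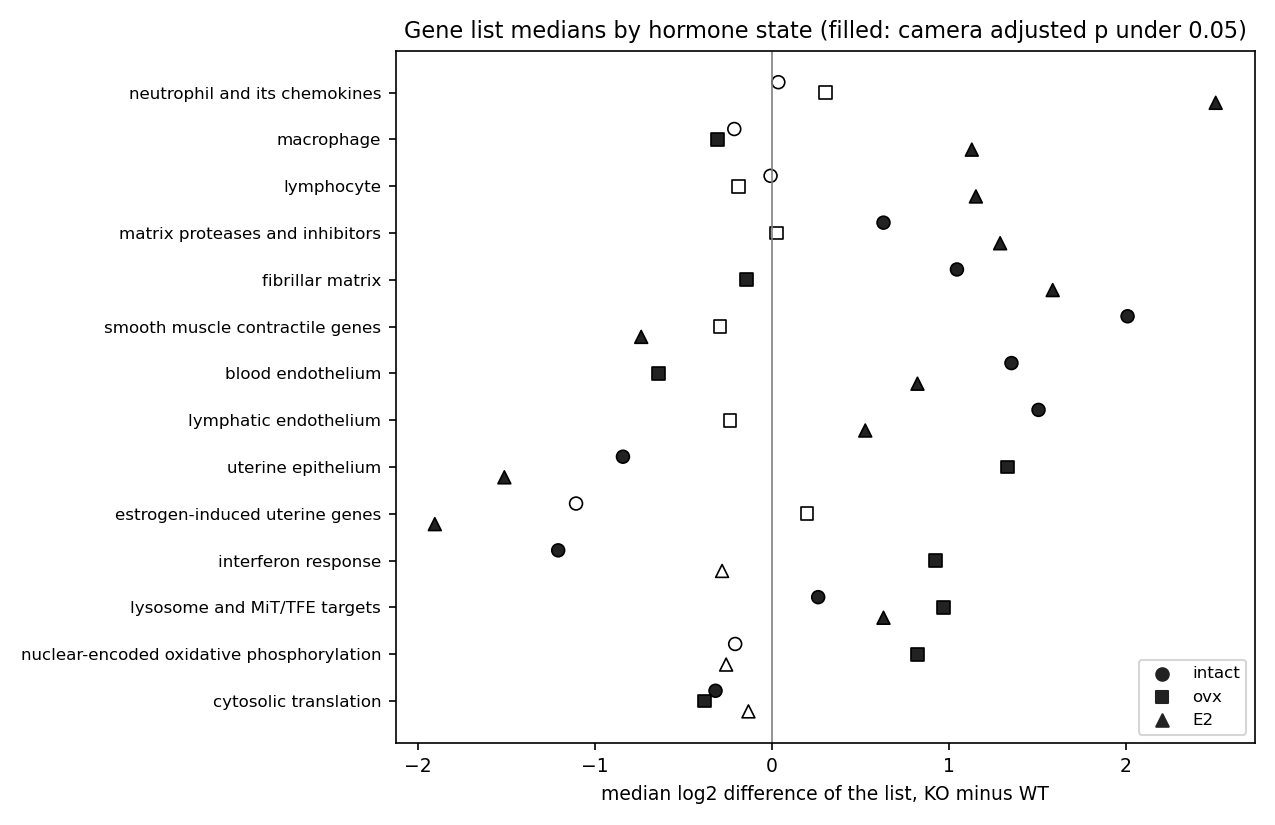
Median log2 difference between KO and WT (horizontal axis) of 14 gene lists (vertical axis) in the intact, ovx and E2 states, filled where the camera adjusted p with the preset correlation was under 0.05. Smooth muscle genes had a median of 2.01 in intact, -0.29 in ovx and -0.74 in E2 uteri, and neutrophil genes 0.04, 0.30 and 2.51.

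Averaged over the 3 hormone states, the lysosome list had more called members than any other list. Of 30 lysosome and MiT/TFE target genes 16 rose and 0 fell (20 adjusted over the list alone). The lysosome median was 0.65 with a camera adjusted p of 1.06e-15 (adjusted p = 0.392 with an estimated correlation). Between 13 and 19 were called with any library left out. Rragd rose by 1.52 ± 0.12, adjusted p = 2.28e-05, Atp6v0d2 by 1.99 ± 0.21, Hexa by 1.23 ± 0.14 and Flcn by 0.69 ± 0.10. The fit with batch as a term called 14 members at a median of 0.64. Of 4 melanocyte lineage genes tested 3 rose, namely Gpnmb (2.14 ± 0.33, adjusted p = 0.00308), Mlana (1.14 ± 0.20) and the transcription factor Mitf (0.67 ± 0.18), the first and last of them also in the lysosome list. Gpx3 rose by 4.08 ± 0.42, adjusted p = 0.000456 over the states, Rnase1 by 2.80 ± 0.41 and Thbs2 by 2.01 ± 0.33, while Fxyd4 fell by 2.77 ± 0.44. For Rragd, Atp6v0d2, Hexa, Gpx3, Thbs2 and Fxyd4 the genotypes also differed in the response to E2 or to ovaries, so that these means do not stand for each state. In the list of TSC-mTOR pathway components 2 of 27 rose, the GTPases Rragd and Rragc (0.70 ± 0.15), with a median of 0.05 (adjusted p = 0.244). Pgr fell by 1.27 ± 0.24 and Esr1 by 0.69 ± 0.19 on the log2 scale, with the Esr1 call lost without 14 of the 18 libraries in turn, and the Wnt ligand gene Wnt7a fell by 1.63 ± 0.31. Neutrophil genes rose in 8 of 19 cases (15 adjusted over the list alone; median 0.96, adjusted p = 7.15e-09, and adjusted p = 0.619 with an estimated correlation), and 13 were called without KO E2 replicate 2. Cytosolic translation genes had a median of -0.27 with an adjusted p of 1.45e-08 (adjusted p = 0.687 with an estimated correlation), although 1 of 34 was called over all genes and 0 adjusted over the list alone. Of 51 named genes called, 34 were called without each of the 18 libraries in turn. Mitf lost its call without any KO intact or WT ovx library, KO ovx replicate 1 or 2, WT E2 replicate 1 or 5, or KO E2 replicate 1 or 3 (adjusted p up to 0.0782). In all 820 genes differed, 579 higher and 241 lower, a higher share of 70.6% that was 52.0% after quantile normalization. The number called ranged from 419 without WT ovx replicate 3 to 1836 without KO E2 replicate 2, and was 603 with batch as a term.

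Estradiol was compared with no hormone in ovariectomized WT mice to give the ordinary estrogen response. Scgb3a1 rose from 0.755 ± 0.929 to 918 ± 588 FPKM (SD, n = 3), a log2 change of 8.88 ± 0.97, adjusted p = 3.35e-05. The iron-siderophore carrier Lcn2 rose by 8.67, from 10.2 ± 7.02 to 4082 ± 712 FPKM (adjusted p = 0.000445). Small proline-rich genes of the Sprr2 family rose together, led by Sprr2f (9.22 ± 1.40), Sprr2e (9.02), Sprr2h (8.97) and Sprr2d (8.95), paralogs whose reads cannot be assigned with certainty. Abp1, a diamine oxidase, rose by 8.59 ± 1.63 and the epithelial protease Mmp7 by 6.91 ± 0.87. Gli1, a hedgehog target, fell from 17.8 ± 0.633 to 0.191 ± 0.129 FPKM (-3.99 ± 0.59, adjusted p = 0.000184), and the stromal genes Islr, Igfbp5, Igfbp3 and Gdf10 changed by -4.15, -3.64, -3.45 and -3.34. Esr1 fell by 1.20 ± 0.33 on the log2 scale, and Pgr did not pass the test (0.69 ± 0.41, adjusted p = 0.174). All called genes of this paragraph were called without each of the 6 libraries in turn.

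Under estradiol in WT mice 21 of 29 estrogen-induced genes rose and 0 fell (22 adjusted over the list alone). The estrogen-induced median was 3.95 with a camera adjusted p of 2.38e-05. Uterine epithelium genes rose in 14 of 20 cases (median 2.06, adjusted p = 0.00255). Squamous epithelium genes rose in 7 of 8 cases (median 3.00 (2.995), adjusted p = 0.0147), with keratins Krt5 (3.64 ± 0.69) and Krt13 (3.17 ± 0.58) among them, uncertain where reads also fit related keratin genes. Glycolysis and hypoxia genes rose in 21 of 27 cases and fell in 1 (median 1.75, adjusted p = 0.00198), including Ldha (3.31 ± 0.46) and Pgk1 (3.26 ± 0.52). Oxidative phosphorylation genes rose in 22 of 26 (23 adjusted over the list alone; median 1.12, adjusted p = 3.71e-05). Interferon response genes rose in 13 of 18 cases (14 adjusted over the list alone; median 2.33, adjusted p = 0.00137), such as Isg15 (3.94 ± 0.58), Irf7 (3.93 ± 0.60) and Oas1a (3.64 ± 0.51). WNT and hedgehog response genes fell in 7 of 11 cases and rose in 1 (median -0.82, adjusted p = 0.000648), such as Axin2 (-1.83 ± 0.36) and Lgr5 (-1.49 ± 0.20). Blood endothelium genes fell in 8 of 14 cases (median -1.07, adjusted p = 8.08e-05) and stromal genes in 6 of 12 (median -1.41, adjusted p = 0.00821). Macrophage genes rose in 9 of 15 cases (10 adjusted over the list alone; median 1.14, adjusted p = 0.0451) and lysosome genes in 16 of 30, with 2 lower (median 1.06, adjusted p = 0.0147). Neutrophil genes rose in 8 of 19 cases (median 0.87, adjusted p = 0.0513), among them Cxcl5 (4.43 ± 0.65), a neutrophil chemokine. Counts adjusted over the list alone equalled those over all genes where none is given, and each of the lists with a camera adjusted p under 0.05 had an adjusted p = 0.673 with an estimated correlation. The endothelial count was 5 and 4 without WT ovx replicates 2 and 3 and 3 without WT E2 replicate 5. The stromal count was as low as 1, without WT E2 replicate 5. Within batches 3 and 4 the medians were 3.96 and 3.93 for estrogen-induced, 2.51 and 1.92 for epithelial, 2.41 and 1.28 (1.275) for glycolysis and 2.90 and 2.07 for interferon genes.

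In WT mice 6599 genes differed between E2 and ovx, 4484 higher and 2115 lower, and 66.7% of genes did not overlap, where chance gives 10%. Median-ratio scaling moved the median gene by -0.28 log2, and the higher share was 67.9% as tested, 47.9% after that scaling and 44.3% after quantile normalization, so the balance of higher and lower genes rests on the scaling. With batch as a term 6698 genes were called, and within batches 3 and 4, with a single E2 and a single ovx library respectively, 4403 and 838.

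The same treatment was compared with no hormone in KO mice. Saa3, an acute-phase protein gene, rose from 109 ± 183 to 10030.0 ± 12092 FPKM (SD, n = 3), a log2 change of 8.18 ± 1.37, adjusted p = 0.00056. The calprotectin genes S100a8 and S100a9 rose by 7.57 ± 1.28 and 7.58 ± 1.21, the paralogs Saa1 and Saa2 by 7.29 and 7.24, haptoglobin (Hp) by 6.94, Slpi by 6.44 and Sprr2b by 7.22. Fxyd2 fell from 146 ± 131 to 2.24 ± 2.11 FPKM (-5.35 ± 0.50, adjusted p = 6.22e-06), and the homeobox gene Msx1, the calcium buffer Calb1, Cyp26a1 and Slc5a11 changed by -4.46, -4.44, -4.34 and -4.23. Esr1 fell by 2.27 ± 0.33 on the log2 scale, Rragd fell by 2.46 ± 0.21 and Atp6v0d2 fell by 3.10 ± 0.37, while Eif4ebp1, a translation repressor and mTORC1 substrate, rose by 2.31 ± 0.42. All of these genes were called without each of the 6 libraries in turn.

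Leukocyte genes rose broadly in KO mice under estradiol. All 19 neutrophil genes rose (median 3.63, camera adjusted p = 6.23e-14). So did 14 of 15 macrophage genes (median 3.00 (2.995), adjusted p = 1.44e-09), such as Csf1r (3.91 ± 0.45) and the complement gene C1qa (4.35 ± 0.57). For both lists the adjusted p = 0.366 with an estimated correlation. Lymphocyte genes rose in 9 of 10 cases (median 1.95, adjusted p = 8.41e-06, and adjusted p = 0.485 with an estimated correlation). Erythrocyte genes rose too, with a median of 2.75 and 3 of 3 called: Hbb-b1 (3.21 ± 0.58) and the near-identical Hba-a1 (2.75 ± 0.55) and Hba-a2 (2.75 ± 0.55). All 3 were called without each of the 6 libraries in turn. Fibrillar matrix genes rose in 15 of 24 cases (18 adjusted over the list alone; median 1.89, adjusted p = 2.69e-06), including Thbs2 (4.05 ± 0.56) and elastin (Eln, 2.31 ± 0.45). Matrix proteases and inhibitors rose in 17 of 25 cases and fell in 1 (18 higher adjusted over the list alone; median 2.15, adjusted p = 6.85e-06), including Timp1 (4.01 ± 0.58) and Plau (2.35 ± 0.27). Estrogen-induced genes rose in 15 of 29 cases and fell in 1 (median 2.21, adjusted p = 0.000279), such as Inhbb (3.33 ± 0.50) and the cell cycle inhibitor Cdkn1a (3.17 ± 0.52). Glycolysis genes rose in 17 of 27 (21 adjusted over the list alone; median 1.24, adjusted p = 4.39e-05). These 4 lists had an adjusted p = 0.63 with an estimated correlation. Smooth muscle genes had a median of -1.36 (adjusted p = 0.000135, and adjusted p = 0.707 with an estimated correlation). Of 18 such genes 4 fell (6 adjusted over the list alone), 12 without KO ovx replicate 4, 2 without KO E2 replicate 3 and 1 without any of the other 4 libraries. Uterine epithelium genes rose in 0 of 20 cases and fell in 3 (median -0.31, adjusted p = 0.113). Of them 6 fell without KO E2 replicate 2, 1 fell without KO E2 replicate 3, and 1 rose and 1 fell without KO E2 replicate 1. Counts adjusted over the list alone equalled those over all genes where none is given. The fibrillar count was 9 without KO ovx replicate 4 or KO E2 replicate 1 or 3, and the glycolysis count 9 and 7 without KO ovx replicates 1 and 2 and 7 without KO E2 replicate 1. In batch 3, which alone holds both states in KO mice, the medians were 2.91 for neutrophil, 3.86 for macrophage, 2.59 for fibrillar matrix and 1.40 for estrogen-induced genes.

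In KO mice 3767 genes differed between E2 and ovx, 2213 higher and 1554 lower, with no overlap at 36.3% of genes, where chance gives 10%. The higher share of 58.7% was 37.8% after quantile normalization, which moved the median gene by -0.12 log2. The number called was 2370 without KO ovx replicate 1, 2727 with batch as a term and 1642 within batch 3, which holds 1 KO E2 library, and 1786 in a fit to these 6 libraries alone.

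Intact and ovx uteri shared no batch, so in the next comparisons the batch and the presence of ovaries cannot be told apart. In WT mice Prap1 stood at 455 ± 356 FPKM in intact and 0.251 ± 0.0592 in ovx uteri (SD, n = 3), a log2 change of 7.76 ± 1.19, adjusted p = 0.000252, and Sprr2f changed by 7.31 ± 1.40. Cell cycle genes were higher in 22 of 27 cases (23 adjusted over the list alone; median 1.23, camera adjusted p = 2.2e-05), such as survivin (Birc5, 2.51 ± 0.34) and Ube2c (2.66 ± 0.41). Estrogen-induced genes were higher in 18 of 29 cases (19 higher and 1 lower adjusted over the list alone; median 3.07, adjusted p = 0.00123) and uterine epithelium genes in 14 of 20 (15 adjusted over the list alone; median 2.32, adjusted p = 0.00334). Smooth muscle genes were lower in 14 of 18 cases (15 adjusted over the list alone; median -2.05, adjusted p = 2.75e-06) and blood endothelium genes in 13 of 14 (14 adjusted over the list alone; median -1.44, adjusted p = 2.75e-06). For all of these lists the adjusted p = 0.852 with an estimated correlation. Without WT intact replicate 4 the smooth muscle count was as low as 4 and the endothelial count 7. All 3 erythrocyte genes were lower as well (median -2.27), Hbb-b1 with an adjusted p of 0.0123 and the near-identical Hba-a1 and Hba-a2 by -2.28 ± 0.55 and -2.27 ± 0.55. Their calls held without each of the 6 libraries in turn. The ribosomal protein gene Rpl36 changed by -4.44 ± 0.46, Dpm3, a subunit of dolichol-phosphate mannose synthase, by -4.01 ± 0.23 and the histone gene Hist1h2ao by -3.98 ± 0.26. In total 6299 genes differed, 4154 higher and 2145 lower in intact mice, with no overlap at 61.0% of genes, where chance gives 10%. The higher share was 65.9% as tested, 52.2% after quantile normalization and 45.4% after median-ratio scaling, which moved the median gene by -0.28 log2.

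In KO mice the intact state differed from ovx in 2206 genes, 992 higher and 1214 lower, with no overlap at 41.1% of genes, where chance gives 10%. Fst stood at 4.17 ± 1.98 FPKM in KO intact and 0.132 ± 0.0470 in KO ovx (SD, n = 3), a log2 change of 2.12 ± 0.21, adjusted p = 1.13e-05. Wif1 changed by 1.94 ± 0.24, Serpinb11 by 3.96 ± 0.50, Inhbb by 3.59 ± 0.50 and the oxytocin receptor Oxtr by 1.88 ± 0.35. Fxyd2 changed by -6.25 ± 0.50, adjusted p = 1.7e-06, Calb1 by -4.82 ± 1.04 and the lysosomal genes Atp6v0d2, Neu1 and Rragd by -2.36, -1.80 and -1.38. Cell cycle genes were higher in 21 of 27 cases (26 adjusted over the list alone; median 1.21, camera adjusted p = 2.07e-11, and adjusted p = 1 with an estimated correlation), such as Rrm2 (1.35 ± 0.28) and Tpx2 (1.46 ± 0.30). The count was as low as 7, without KO ovx replicate 2. Lymphatic genes were higher in 3 of 8 cases, also adjusted over the list alone (median 1.10 (1.095), adjusted p = 0.0127, and adjusted p = 1 with an estimated correlation). They were Flt4 (1.44 ± 0.29), Lyve1 (2.01 ± 0.45) and Mmrn1 (1.92 ± 0.46), the last with an adjusted p of 0.0625 without KO intact replicate 3 and 0.0592 without KO ovx replicate 2. The other genes named here were called without each of the 6 libraries in turn. The number of genes called was 1260 and 1295 without KO intact replicates 3 and 4 and 1167 and 1241 without KO ovx replicates 1 and 2. Median-ratio scaling moved the median gene by -0.12 log2, and the higher share was 37.2% after it and 52.2% after quantile normalization.

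Overlaps addressed the genes that the series title calls estrogen- and mTORC1-dependent. Of 682 genes higher in KO E2 than in WT E2, 560 were also higher in KO E2 than in KO ovx (82.1%). Independent lists would share 108.6, and simulated unchanged groups shared 0.01 on average and at most 1. At an unadjusted p the overlap was 1059 against a simulated mean of 75.3 and maximum of 96. By the smaller of the log2 changes, the genes that rose most in both were Camp (5.09), Ngp (5.04), Slpi (4.35), Stfa3 (4.15), Stfa2l1 (4.02), Stfa2 (3.92), Thbs2 (3.83), Mmp13 (3.79), Retnlg (3.60) and Ccl8 (3.51). Here as in intact mice, the shared KO libraries may give part of the excess, which simulations without any change cannot gauge. The overlap was 283 and 363 without WT E2 replicates 1 and 5, 369 without KO E2 replicate 1, 1019 without KO E2 replicate 2 and 489 with batch as a term. For the intact state, 60 of 165 genes higher in KO than in WT were also higher in KO intact than in KO ovx (36.4%), against 11.8 for independent lists and 0 in 100 simulations. At an unadjusted p it was 358 against a simulated mean of 77.3 and maximum of 96. By the same measure these were led by Serpinb11 (3.44), Clu (2.97), Cldn2 (2.87), Inhbb (2.78), Aspn (2.45), C1qtnf3 (2.44), Mustn1 (2.42), Serpinb7 (2.23), Fst (2.12), Akr1c14 (2.08) and Lyve1 (2.01). That overlap was 29 without WT intact replicate 4, 38 and 16 without KO intact replicates 1 and 3 and 35 without KO ovx replicate 1.

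Differences between the genotypes in their response were tested directly. For the response to estradiol 1529 genes differed, 563 with a more positive and 966 with a more negative change in KO, and Camp (4.67 ± 0.76, adjusted p = 0.0038) and Scgb3a1 (-6.77 ± 1.37, adjusted p = 0.00984) were among the largest. Uterine epithelium genes had the more negative change in 11 of 20 cases (17 adjusted over the list alone; median -2.85, camera adjusted p = 3.31e-07). Neutrophil genes had the more positive one in 10 of 19 (13 adjusted over the list alone; median 1.99, adjusted p = 5.72e-10), and both lists had an adjusted p = 0.438 with an estimated correlation. Rragd (-2.36 ± 0.29), Neu1 (-2.84 ± 0.44) and Atp6v0d2 (-3.30 ± 0.53) had the more negative change. For the presence of ovaries 643 genes differed, 142 more positive and 501 more negative in KO. Among them were Fst (2.38 ± 0.30, adjusted p = 0.00209), Wif1 (2.49 ± 0.34), Cyp26a1 (-4.58 ± 0.74) and Prap1 (-8.82 ± 1.68). Endothelial genes had the more positive change in 8 of 14 cases (14 adjusted over the list alone; median 2.03, adjusted p = 5.71e-14, and adjusted p = 0.321 with an estimated correlation). Median-ratio scaling moved the median gene by 0.21 for the estradiol response and 0.16 for the ovaries, and the more positive share went from 36.8% to 52.7% and from 22.1% to 36.4%, or 46.9% for the ovaries after quantile normalization. The estradiol count ran from 520 without WT ovx replicate 1 to 2383 without KO E2 replicate 2, and was 1154 with batch as a term and 236 within batch 3, with 1 E2 library of each genotype. For the ovaries it ran from 87 without WT ovx replicate 1 to 1178 without WT intact replicate 1, and was 389 with batch as a term. The epithelial count for estradiol was as low as 3, without WT ovx replicate 1 or WT E2 replicate 5. The endothelial count for the ovaries was as low as 1, without WT ovx replicate 1 or 3 or KO ovx replicate 4.

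With either other scaling, median-ratio or quantile, the median of each list called by camera kept its sign in every comparison.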

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

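The tests of explanations for the neutrophil pattern and for the muscle and vessel pattern were chosen only after the result was seen, while the counts over other splits of the libraries were set before. What set the genes and lists apart was a difference between WT and KO mice in their response to estradiol or to the presence of ovaries, by a test of the difference itself in limma or camera.

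For the response to estradiol, 1529 genes had a change that differed between the genotypes. The change was more positive in KO mice for Camp (4.67) and Ngp (4.39), both neutrophil granule genes, for the chemokine Cxcl12 (4.33), for Mgp (3.87), which encodes the matrix Gla protein, and for the cytokine receptor Csf2rb2 (3.77). It was more negative for Scgb3a1 (-6.77), Pdzk1ip1 (-6.43), Fcgbp (-6.40), the calcium buffer Calb1 (-6.12) and the mitochondrial creatine kinase Ckmt1 (-5.89). The calls of Camp, Csf2rb2, Scgb3a1, Pdzk1ip1 and Ckmt1 held without each of the 12 libraries in turn. The call of Ngp ended without WT ovx replicate 1, KO ovx replicate 1 or WT E2 replicate 1 (adjusted p up to 0.0565), and that of Fcgbp without WT ovx replicate 1 or 2, KO ovx replicate 4 or WT E2 replicate 1 or 5 (up to 0.0686). That of Calb1 ended without WT ovx replicate 1, KO ovx replicate 4, WT E2 replicate 5 or KO E2 replicate 1 (up to 0.0544). Those of Cxcl12 and Mgp ended without any WT ovx library, KO ovx replicate 4, WT E2 replicate 1 or 5 or KO E2 replicate 1 or 3 (up to 0.083 and 0.0911), and for Mgp also without KO ovx replicate 1. Of the gene lists, the more positive change in KO fell on neutrophil (1.99), matrix protease (1.57), fibrillar matrix (1.51), macrophage (1.51), blood endothelium (1.504), adipocyte (1.63), stroma (1.34), lymphocyte (1.20), contraction (0.91), lymphatic (0.87) and translation genes (0.21), given as list medians. The more negative one fell on uterine epithelium (-2.85), estrogen-induced (-1.69) and oxidative phosphorylation genes (-1.16). With an estimated correlation the lowest adjusted p among these lists was 0.438.

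For the presence of ovaries, 643 genes had a change that differed between the genotypes, or 389 with batch as a term. The change was more positive in KO mice for Cldn5 (3.74), fibronectin (Fn1, 3.73), Des (3.57), Mustn1 (3.53) and Serpinb11 (3.28), and more negative for Prap1 (-8.82), Pdzk1ip1 (-6.53) and the paralogs Serpina1e (-6.40), Serpina1b (-6.35) and Serpina1c (-6.35). The calls of the last 5 genes held without each of the 12 libraries in turn. The calls of Cldn5, Fn1 and Des ended without any WT ovx library, KO ovx replicate 1 or 4, WT intact replicate 4 or KO intact replicate 3 (adjusted p up to 0.0789, 0.0959 and 0.0968). For Cldn5 and Des they also ended without KO intact replicate 1, and for Fn1 without WT intact replicate 2 or KO intact replicate 4. That of Mustn1 ended without KO intact replicate 1 or 3, WT ovx replicate 1 or KO ovx replicate 4 (up to 0.0617), and that of Serpinb11 without WT ovx replicate 1 or KO ovx replicate 1 (up to 0.0716). List medians were more positive in KO for smooth muscle (2.50), blood endothelium (2.03), stroma (1.88), lymphatic (1.76), fibrillar matrix (1.40), WNT and hedgehog response (1.09), eosinophil and mast cell (0.86) and matrix protease genes (0.80). They were more negative for uterine epithelium (-2.30), interferon response (-2.20), squamous epithelium (-2.08), oxidative phosphorylation (-1.05) and lysosome genes (-0.81). With an estimated correlation the lowest adjusted p among these lists was 0.321.

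Neutrophil genes were higher in KO E2 than in WT E2 uteri. A technical batch as the whole cause is argued against by the median of 2.84 within batch 4, with 2 libraries against 2, and by the E2 libraries, which fall in the 2 batches alike in both genotypes. In batch 3, with only 1 library against 1, the median was the lower of the 2 at 1.67 (1.669). Blood of unchanged makeup left in the tissue remains open. The neutrophil mean less the erythrocyte mean was -0.70 and -0.79 in KO E2 replicates 1 and 2 but -3.25 in replicate 3, against -2.58, -3.21 and -2.12 in WT. The mean difference was 1.06 (1.057), and the values overlapped. The 3 erythrocyte genes had a median of 1.41. A biological explanation, more neutrophils in the KO tissue under estradiol, may also account for the pattern and was not tested by any count of cells.

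Smooth muscle and endothelial list medians, with few genes called, were higher in KO intact uteri. Without WT intact replicate 4, which stood apart, no call was left, but the lower median was 1.10 (1.099), so it was not the whole cause. A smaller share of epithelium in the tissue pieces would raise the markers of all other cell types alike. The smooth muscle median exceeded the highest of the stroma, macrophage and lymphocyte medians by 1.22 (1.219), more than the interquartile range of 1.03 among its members. The mean log2 level of the 3 erythrocyte genes was 4.07, 4.60 and 3.76 in KO intact against 1.69, 2.32 and 1.56 in WT intact libraries. There was no overlap, so blood content moved with the vessel genes. A larger share of muscle and vessels, in the animal or pieces taken, or estrous stage may explain the pattern and was not tested.

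The 10 splits of 3 against 3 libraries are too few for a share under 0.05. Counts for the real one and the highest other were 303 and 1 for KO against WT intact. They were 753 and 2 for ovx and 1180 and 20 for E2. They were 6599 and 0 for E2 against ovx in WT, 3767 and 16 in KO, 6299 and 1 for intact against ovx in WT, and 2206 and 6 in KO. For the mean over states the real one of 100 splits called 820 and the next 279, so chance between libraries is unlikely. The real one led for the differences in response (1529 against 237, 643 against 265) and the KO intact overlap (60 against 34). Those splits mix other group differences, so chance in response or genotype stays open. For the 560 genes higher in KO E2 than in both other groups, 3 of 100 splits gave as many. The highest others gave 993, 967 and 31 genes. Those with 993 and 967 set the KO ovx libraries against E2 libraries of mixed genotype, so they follow estradiol and leave chance between genotypes open.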

How the results depend on the processing

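The batch term, the fits within batches and the removal of WT intact replicate 4 with KO ovx replicate 4 were chosen after seeing the data, and the other alternatives were set before. Depth is unknown, and with 3 libraries a group a single library can carry a call. For each changed value the cause was not tested, except that a minimum mean of 5 FPKM tests fewer genes and a 2-fold minimum adds a condition.

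With a mean of at least 5 FPKM the genes called numbered 104 for KO against WT intact, 490 for ovx, 306 for E2 and 252 for the mean over states. They numbered 3040 and 1386 for E2 against ovx in WT and KO, 2909 and 1001 for intact against ovx in WT and KO, and 594 and 410 for the genotype differences in the response to E2 and to ovaries. The genes higher in KO E2 than in both other groups numbered 95, and those higher in KO intact 12, or 96 with no minimum. Requiring 2-fold left 429 for ovx, 194 for the mean, 3528 and 2094 for E2 against ovx in WT and KO, and 3162 and 992 for intact against ovx in WT and KO.

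Median-ratio scaling gave 1263 genes for the mean over states. Quantile normalization gave 560 for intact, 1985 for ovx, 1616 for the mean, 3682 for intact against ovx in KO, 1535 for the difference in response to ovaries and 108 for the genes higher in KO intact than in both other groups. Under quantile normalization 4 called changes of E2 against ovx changed sign: Rpl27 (-0.35), Eef1b2 (-0.27) and Eif3e (-0.38) in WT, and Rpl27 (-0.19) in KO. So did Cox4i1 in KO, from 0.26 without a call to -0.47.

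A fit to only the groups compared gave 25 genes for intact and 0 for E2 (limma, with 2473 at an unadjusted p under 0.05). It gave 1786 for E2 against ovx in KO, and 150 and 18 for the genes higher in KO E2 and in KO intact than in both other groups. A replicate block gave 545 for intact, 399 for ovx, 384 for E2 and 482 for the mean. It gave 136 and 397 for the differences in response to E2 and ovaries, and 232 for the genes higher in KO E2 than in both. Replicate numbers did not pair the libraries, so the block has no basis in the design. With batch as a term 429 genes were called for ovx and 389 for the difference in response to ovaries. Within batches the counts were 19 and 5 for intact (batches 1 and 2), 152 for ovx (batch 3), and 279 and 18 for E2 (batches 3 and 4). They were 838 for E2 against ovx in WT (batch 4), 1642 in KO (batch 3) and 236 for the difference in response to E2 (batch 3). Without the 2 libraries that stood apart, E2 gave 1894 and the difference in response to ovaries 199. Of 120 list calls in camera, 0 held with an estimated correlation.

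Leaving out each library in turn gave 66 to 674 genes for intact, 149 to 912 for ovx, 517 to 2235 for E2 and 419 to 1836 for the mean over states. For E2 against ovx it gave 4889 to 5945 in WT and 2370 to 4326 in KO, and for intact against ovx 4256 to 6077 in WT and 1167 to 2700 in KO. The ranges were 520 to 2383 and 87 to 1178 for the differences in response to E2 and to ovaries. They were 283 to 1019 and 16 to 90 for the genes higher in KO E2 and in KO intact than in both other groups, and -0.21 to -0.15 for the log2 difference of Tsc2.

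Of 702 calls of named genes, 634 held with a pseudocount of 0.1, 595 with no filter, 672 with median-ratio scaling, and 668 with quantile normalization. Of the same calls 528 held with only the groups compared, 507 with a replicate block, 689 with a robust fit and 609 without the 2 libraries that stood apart. With batch as a term 444 of 527 held. Without a library of the comparison, 120 to 149 of 211 held in KO intact, 174 to 226 of 244 in WT intact, 280 to 325 of 409 in WT ovx, 263 to 302 of 367 in KO ovx, 195 to 252 of 294 in WT E2 and 182 to 269 of 285 in KO E2. The Tsc2 difference was -0.25 (-0.252) with a pseudocount of 0.1, -0.19 with median-ratio scaling and -0.25 (-0.247) with quantile normalization.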

Other observations

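In the histone pattern, the tests of dividing cells and of batch were chosen only after the result was seen, and the test of short transcripts was set before. Several genes with large differences were carried by KO ovx uteri. Cyp26a1, which degrades retinoic acid, stood at 33.1 ± 36.9 FPKM in KO ovx, against 0.122 ± 0.0514 in WT ovx, 0.146 ± 0.0681 in KO E2 and 0.460 ± 0.0873 in KO intact uteri (SD, n = 3). The genotypes differed in its response to estradiol (-4.21 ± 0.74, adjusted p = 0.00492) and to ovaries (-4.58 ± 0.74, adjusted p = 0.00655). Fxyd2, a subunit of the sodium pump, stood at 146 ± 131 FPKM in KO ovx and 1.09 ± 0.421 in WT ovx, and Slc5a11, a sodium-coupled inositol transporter, at 18.4 ± 4.57 and 0.0827 ± 0.0596. Tnni2, a fast skeletal troponin, was lower in KO ovx uteri (-2.63 ± 0.31, adjusted p = 0.000259), which carried its mean over the states (-0.96 ± 0.18), as it changed by -0.39 in intact and 0.15 in E2 uteri without a call. In contrast, Ckm, the muscle creatine kinase, was higher in KO ovx uteri (1.87 ± 0.34, adjusted p = 0.00586). Gata2, a transcription factor of the progesterone response, was lower in KO over the states (-0.68 ± 0.14), and the WNT antagonist gene Sfrp4 was higher (1.57 ± 0.32), but in ovx uteri they changed by 0.10 and -0.04 without a call. All of these called values held without each library in turn.

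Averaged over the states, further lists moved, with counts that single libraries changed. Epithelium, endothelium, smooth muscle and interferon medians differed in sign between states, which their means hide. Matrix proteases rose in 5 of 25 cases (12 adjusted over the list alone; median 0.69, camera adjusted p = 2.26e-06, or 0.619 with an estimated correlation), or 15 without KO E2 replicate 2. Fibrillar matrix genes rose in 5 of 24 cases (10 adjusted over the list alone; median 0.85, adjusted p = 2.26e-06 and 0.687 likewise). There were 12 without KO E2 replicate 2 and 8 without WT intact replicate 1. Without most others either count was 2 or 3. Estrogen-induced genes fell in 4 of 29 cases (2 higher and 7 lower adjusted over the list alone; median -1.04, adjusted p = 0.000107 and 0.687 likewise). With any library left out there were 2 to 9. Medians of other lists called by camera were 0.73 for lymphatic genes (adjusted p = 0.000436, or 0.619 with an estimated correlation), 0.31 for cell cycle (0.000291 and 0.751), and 0.45 for blood endothelium (0.000291 and 0.687). They were -0.55 for uterine epithelium (0.00917 and 0.751), -0.12 for steroid receptors (0.0251 and 0.619), 0.32 for lymphocytes (0.0371 and 0.748) and 1.31 for adipocytes (0.0098 and 0.748). Not called were sterol synthesis (median 0.12, adjusted p = 0.32), glycolysis (0.02, 0.736), ATF4 and amino acid genes (0.09, 0.847), progesterone-induced genes (-0.04, 0.992), smooth muscle (0.36, 0.113) and contraction genes (0.42, 0.0937). Nor were squamous epithelium (-0.35, 0.469), stroma (0.29, 0.559), macrophage (0.20, 0.244), eosinophil and mast cell (-0.15, 0.269), immediate early (-0.35, 0.317), interferon response (-0.26, 0.468), oxidative phosphorylation (0.13, 0.0733) and WNT and hedgehog response genes (0.07, 0.32). Lists too short for camera were ovary and oviduct (3 genes, median -0.02), skeletal muscle (4 genes, 0.09) and erythrocyte (3 genes, 1.06).

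Histone genes that are copied in S phase were low in intact uteri of both genotypes. Of 63 such genes, 40 were lower and 5 higher in intact than in ovx WT uteri (median -0.95), and 40 lower and 0 higher in KO (median -1.61). Fewer dividing cells are argued against by the cell cycle list, the lower of whose medians over the genotypes was 1.21 (1.212). A loss of short transcripts is argued against by the other 366 genes under 600 nt, set against 3257 genes of 1000 to 3000 nt, since the higher of the differences of their medians over the genotypes was -0.04 (-0.039). A technical batch may be the cause and cannot be told apart from the state, as the highest intact library lay below the lowest ovx library by a difference of -0.72 (-0.715) in mean log2 level.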
